A study of Mus musculus with 6 samples.

How the data were processed

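The intensity values used were the processed signals of the scanner's feature files, which per the file headers were made by Agilent Feature Extraction 10.7.3.1 with spatial and multiplicative detrending switched on, while the submitters' processing notes name version 9.3.2.1. The deposited value table equals the mean of those processed signals within 0.1% for 99.67% to 99.77% of probes; its column medians run from 27.52 to 52.12, so it is on the linear scale and not centred, a scale found by comparison with the feature files. The array design is 026655, with probe coordinates on mm9. No genome was used. Gene names came from the files, and 26055 of 39429 probes took the symbol of their RefSeq accession in the mouse reference used for names alone; 32334 probes carry such an accession, and 3358 names changed. Names in the form of an accession were not treated as ordinary symbols; 13895 of the features tested have an ordinary symbol.

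From the intensity of 43020 spots per array that are not controls, spots marked as outliers by the scanner software were left out (127 to 251 per array), log2 was taken, the spots of a probe were averaged and the array's 75th percentile was subtracted. Of 39429 probes 24234 were kept because they were well above background on all measured arrays of at least 1 diet, and the probe with the highest mean signal for each gene name gave 19616 features. The diets were compared with limma's moderated test and Benjamini-Hochberg adjustment, and a gene was called at adjusted p under 0.05. The 36 gene lists hold 939 members, of which 10 matched no probe, and were tested with camera at a correlation of 0.01, again with an estimated correlation, and with fry; members were also adjusted over the list alone. The lists, the main settings and most alternatives were fixed before the data were examined. The fit on slide 1 alone was added afterwards, and it takes the lone restricted mouse to vary like the control mice.

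The genes named were fixed by a rule: the targets of the vector, a set of metabolic and growth genes always given, the 12 genes with the largest difference in each direction among called genes with an ordinary symbol and no overlap between the diets, and up to 4 called members of each list with the smallest p, or 2 members where none was called. Some genes that the rule names are not reported here. Where a probe was not well above background in any mouse of a group, or saturated in all, only a bound is given: the mean of the brighter group against the mean, over the dimmer group's arrays, of the higher of the probe's own signal and the lowest signal among probes well above background; for saturated probes the bound is the measured ratio. Where a probe was dim on some arrays of a group only, the same floor was applied to each array, and genes were ranked by the fitted difference. Among called features, 57 were not well above background in all control arrays and 456 in all restricted arrays. Features saturated on all arrays of both groups number 109.

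A simulation drew on the means and spread of these arrays. In it 88 of 100 features with a log2 difference of 2 and 11 of 100 with a difference of 1 were recovered. A small share of its features was changed, against 27.5% called in the data. That makes the adjusted threshold stricter there, so these counts do not give the power of the comparison of diets. Of 107 features called there, 8 had no true change. Of 5 lists of 25 shifted by 0.5, 5 were called, and none of 15 unshifted lists was. Features were drawn independently of each other there, so these lists do not check camera on lists of correlated genes.

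Alternatives tried were normexp background correction, quantile normalization, median scaling, the deposited value table, no background filter, probes well above background on all arrays, trend and robust moderation, array weights, mouse number as a block, slide as a block, slide 1 alone, leaving out each mouse, every probe, an ordinary pooled test, and other thresholds. The normexp setting added an offset of 50 to each signal. Median processed signals of the arrays were 27.5 to 52.0, so the offset shrinks log2 differences of dim probes. Software was R 4.3.3, limma 3.58.1 and data.table (version 1.17.8).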

Results

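Gene expression was measured in liver tissue outside the tumours of 6 male C57BL/6 mice, an inbred laboratory strain, that carried an induced liver cancer model. The mice were 5 weeks old at the start and were assigned at random to a control diet (3 mice) or a diet with moderately restricted carbohydrate (3 mice). All received, by hydrodynamic injection (a rapid large-volume injection into the tail vein that carries DNA into liver cells), a transposon vector encoding an activated human HRAS, a short hairpin RNA against mouse p53 and green fluorescent protein. The labels conflict on the feeding: the sample labels give 1 week of preliminary feeding and 5 weeks of diet, and the text of the series gives 2 weeks and 4 weeks. They also conflict on the diet. The title and design text of the series add plant compounds meant to mimic calorie restriction, and the sample labels name only the carbohydrate restriction. The sample titles use the word supplemented for both diets and name no supplement. Each mouse gave 1 single-colour array. The 75th percentile of signal ranged from 287 to 574 over the 6 arrays, and between 23527 and 25816 of 39429 probes were well above background on an array. The number of arrays, 3 per diet, limits the precision of every value.

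The question was how gene expression in the liver tissue outside the tumours differed between the diets. Genes of myeloid cells, antigen presentation and cell division were lower in mice on the restricted diet and genes of mitochondrial respiration, fatty acid breakdown, bile acid synthesis, detoxification and male-biased liver function were higher. None of the gene lists behind this statement passed with an estimated correlation (lowest adjusted p = 0.238). Of 19616 features tested, 5386 changed (27.5%), of which 2868 were higher and 2518 lower in the restricted group. At least a 2-fold difference was seen for 1572 of those higher and 2056 of those lower. The arrays of the 2 diets lay apart on the first principal component, which held 70.2% of the variance, and correlations across features were 0.976 to 0.988 within a diet and 0.925 to 0.947 between diets. The signal ranges of the diets did not overlap for 8794 features (44.8%), against 10% by chance for 3 against 3. The median feature was 0.12 higher on the log2 scale in the restricted group. Medians of gene lists are therefore given after subtracting this 0.12, and values of single genes are log2 differences (restricted minus control) as fitted, with the SE and limma's adjusted p, 3 mice per diet.

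The mouse counterparts of the injected oncogene and of the hairpin's target did not pass the test. The Hras probe (NM_008284, mm9 chromosome 7, 148377296 to 148377355) measured 1.22 ± 0.44 on the control diet and 1.61 ± 0.26 on the restricted diet (mean log2 signal relative to the array's 75th percentile ± SD, n = 3 each), a difference of 0.39 ± 0.27 (SE, adjusted p = 0.322). Per mouse its values were 1.68, 1.16 and 0.82 on the control diet and 1.68, 1.82 and 1.32 on the restricted diet. The Trp53 probe (NM_011640, mm9 chromosome 11, 69404204 to 69404263) measured -3.19 ± 0.58 and -3.39 ± 0.33, a difference of -0.20 ± 0.33 (adjusted p = 0.686), and its sign turned to 0.11 with normexp background correction and to 0.13 without control mouse 3. Per mouse the Trp53 values were -3.44, -3.61 and -2.52 on the control diet and -3.62, -3.54 and -3.01 on the restricted diet. Both groups carried the vector, so neither probe checks the diet labels, and whether the Hras probe also reads the human transgene is not known.

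**Figure D1:**
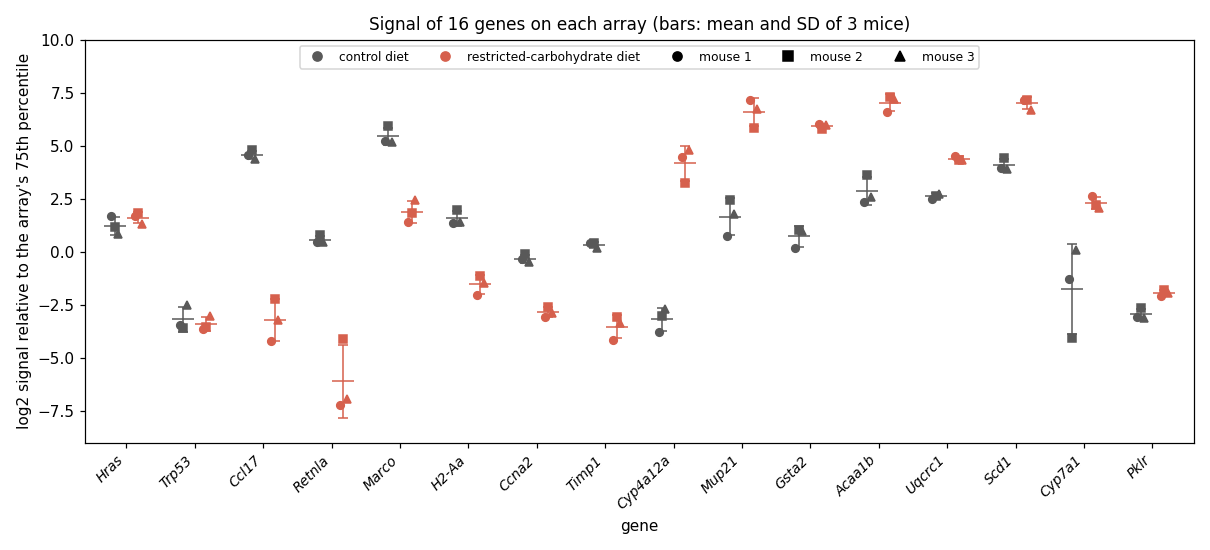
Log2 signal relative to the array's 75th percentile (vertical axis) for 16 genes (horizontal axis) in each of the 6 mice, with symbols for mouse number, long dashes for group means and bars for the SD of 3 mice. Hras and Trp53 overlap between the diets, Ccl17 lies between 4.39 and 4.78 on the control diet and between -4.20 and -2.22 on the restricted diet, and Cyp4a12a lies at or below -2.72 on the control diet and at or above 3.25 on the restricted diet.

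The 12 largest decreases were in genes of different kinds, among them 2 chemokines and 2 products of macrophages. Ccl17, a chemokine that attracts T cells, measured 4.58 ± 0.20 on the control diet and -3.21 ± 0.99 on the restricted diet (SD, n = 3 each) and fell by 7.78 on the log2 scale (SE 0.46, adjusted p = 0.000273; probe on mm9 chromosome 8, 97335770 to 97335829). Cxcl14, another chemokine, fell by 6.87 (SE 0.46), and of Retnla and Chil3, secreted by alternatively activated macrophages, Chil3 fell by 6.32 and Retnla was at least 38.3-fold lower with dim arrays at their floor. Slc13a5, a citrate transporter, fell by 5.85 (SE 0.20, adjusted p = 0.000176), and its other probe by 6.09. Cd209c, a lectin receptor, and Vdr, the vitamin D receptor, were at least 31.4-fold and 28.0-fold lower in the same way, while the other probe of Cd209c measured -3.72. Retnla, Cd209c and Vdr were each well above background on 4 of the 6 arrays. A further 5 genes were not well above background in any mouse on the restricted diet and have only a bound: Adra2a, an adrenergic receptor, was at least 48.2-fold lower, Ffar2, a receptor for short-chain fatty acids, at least 30.5-fold, Ltf (lactoferrin) at least 26.4-fold, Slc52a3, a riboflavin transporter, at least 18.5-fold, and Htr7, a serotonin receptor, at least 9.92-fold lower. Adjusted p over these 12 genes was at most 0.00212.

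The 12 largest increases were in genes of different kinds, among them 3 of the Cyp4a family of cytochromes P450. Cyp4a12a, a fatty acid hydroxylase of male mouse liver, measured -3.18 ± 0.54 on the control diet and 4.17 ± 0.82 on the restricted diet (SD, n = 3 each), a difference of 7.35 ± 0.45 (SE, adjusted p = 0.000303; probe on mm9 chromosome 4, 115005258 to 115005317). Its near-identical neighbour Cyp4a12b rose by 7.21, and the related Cyp4a32 by 4.98, and signal shared within this family cannot be separated. Pax2, a transcription factor of kidney and eye development, rose by 6.43 ± 0.62 and Car3, a carbonic anhydrase abundant in liver and fat and saturated on 1 array, by 6.17 ± 0.68. Sult2a8, a sulfotransferase, rose by 5.40, Gsta2, a glutathione transferase, by 5.21, Mup21, a major urinary protein, by 4.93, Krt23, a keratin, by 4.78, and Acot1, a cytosolic acyl-CoA thioesterase, by 4.73. Slc13a2, a dicarboxylate transporter, was at least 25.6-fold higher with dim arrays at their floor and was well above background on 4 of the 6 arrays. Clec2h, a lectin-like gene, was at least 20.8-fold higher in the same way (adjusted p = 0.0124 as fitted), with a control SD of 2.19 and signal well above background on 5 of the 6 arrays. Adjusted p was at most 0.00171 for the other 11 genes.

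Antigen presentation genes fell without exception. All 15 measured members of the MHC class II list fell (15 also adjusted over the list alone), with a median of -3.29. H2-DMb1 fell by 4.07, H2-DMa by 3.83, H2-Aa by 3.12 and Ifi30, a lysosomal reductase, fell by 3.22, with adjusted p from 0.000579 to 0.000639. The list passed camera at adjusted p = 6.92e-12 (adjusted p = 0.238 with an estimated correlation). Of the macrophage and Kupffer cell markers, 22 of 25 fell and none rose (22 adjusted over the list alone), with a median of -2.36 and camera adjusted p = 1.17e-14 (adjusted p = 0.238 with an estimated correlation). Marco, a scavenger receptor, fell by 3.55 ± 0.33, Fcer1g fell by 2.95 ± 0.18, Tyrobp by 2.83 ± 0.23 and Vsig4, a complement receptor of Kupffer cells, by 2.78 ± 0.26.

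Granulocyte and cytokine genes were lower as well. Of 20 measured neutrophil and granulocyte markers 14 fell and 1 rose (16 and 2 adjusted over the list alone), with a median of -3.46. Prtn3, a neutrophil protease near background in the restricted group (well above it on 4 of the 6 arrays), was at least 34.6-fold lower with dim arrays at their floor, and Camp, an antimicrobial peptide gene, fell by 3.57 ± 0.40. The list passed camera at adjusted p = 2.22e-07 (adjusted p = 0.272 with an estimated correlation), and its median was -1.59 with the slide as a block and -1.76 with normexp background correction. Of 20 measured inflammatory cytokine and NF-kB target genes 13 fell and none rose (15 adjusted over the list alone), with a median of -1.77, or -1.52 with dim genes at their bounds and -1.05 with normexp background correction. Il6 fell by 3.59, Tnfaip3, a brake on NF-kB, by 2.61 and Tgfb1 by 1.97. Tnf was at least 2.35-fold lower, and its call ended with normexp background correction (adjusted p = 0.274), whose offset shrinks differences of dim probes. The list passed camera at adjusted p = 1.18e-07 (adjusted p = 0.246 with an estimated correlation).

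Lymphocyte, interferon and acute phase lists were lower by less in the main fit, a comparison between lists that was not tested. Of 23 measured T and NK cell markers 10 fell and 1 rose (14 and 2 adjusted over the list alone), with a median of -1.04 and camera adjusted p = 0.000875 (adjusted p = 0.44 with an estimated correlation); the median was -0.47 with normexp background correction. Klrd1, a receptor of NK cells, fell by 2.36, Cd2 by 2.37 (its other probe measured -1.49), and Il7r, well above background on 4 of the 6 arrays, was at least 4.92-fold lower with dim arrays at their floor. Cd6 fell by 1.98, while its other probe measured 0.81. Of 15 measured B and plasma cell markers 6 fell and 1 rose (7 and 1 adjusted over the list alone), among them Btla, which fell by 2.00, and Vpreb3, which rose by 2.26. That list had a median of -1.06 and camera adjusted p = 0.00493 (adjusted p = 0.423 with an estimated correlation); the median was -0.64 without restricted mouse 1, -0.41 with normexp background correction, -0.58 without the background filter and -1.65 with the slide as a block. Of 32 measured interferon response genes 8 fell and none rose (10 fell and 1 rose adjusted over the list alone), including Oas1a, which fell by 2.09, and Oas2, which fell by 1.94. The interferon list had a median of -0.68 and camera adjusted p = 0.00438 (adjusted p = 0.583 with an estimated correlation); the median was -0.41 without restricted mouse 1, -0.45 without control mouse 2, -0.38 with normexp background correction and -1.43 with the slide as a block. Of 26 acute phase genes 8 fell and 1 rose (10 and 1 adjusted over the list alone). Orm3, an acid glycoprotein, fell by 3.03 and Hamp2, a relative of the iron hormone hepcidin, rose by 3.74. The acute phase list had a median of -1.11 and camera adjusted p = 0.00455 (adjusted p = 0.423 with an estimated correlation), and with the slide as a block its median was -0.19 and its adjusted p = 0.301.

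Cell division genes were lower in the restricted group. Of 33 measured cell cycle genes 28 fell and none rose (29 adjusted over the list alone), with a median of -2.12, or -1.18 with normexp background correction. Ccna2, a cyclin of S phase and mitosis, fell by 2.51 ± 0.20, Cdkn3 by 2.43 ± 0.22 and Ccnd1, a cyclin of G1 phase, by 2.67 ± 0.38. Bub1b, a spindle checkpoint kinase well above background on 4 of the 6 arrays, was at least 3.23-fold lower with dim arrays at their floor. Bub1 was at least 3.70-fold lower. Neither passed with normexp background correction (adjusted p = 0.277 and 0.078), whose offset shrinks differences of dim probes. The list passed camera at adjusted p = 1.84e-17 (adjusted p = 0.238 with an estimated correlation). Macrophage and antigen presentation markers were lower in the same samples, as given above.

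Oncofetal and RAS-pathway lists had lower medians. Of 22 measured oncofetal and liver progenitor genes 11 fell and 4 rose (12 and 5 adjusted over the list alone), with a median of -1.99, or -1.45 with dim genes at their bounds and -0.995 with normexp background correction. Those with the smallest p were Cd24a, a surface glycoprotein, which fell by 3.82, S100a6, a calcium-binding protein, by 3.58, S100a11 by 3.09 and Anxa2, a membrane-binding annexin, by 2.87, all of which leukocytes and stroma also express. Afp, the fetal liver protein used as a tumour marker, rose by 1.52 ± 0.28 (adjusted p = 0.00775). The list passed camera at adjusted p = 0.00142 (adjusted p = 0.341 with an estimated correlation). Of 24 measured RAS-ERK feedback and immediate-early genes 10 fell and 1 rose (12 and 1 adjusted over the list alone), with a median of -0.98 and camera adjusted p = 1.49e-05 (adjusted p = 0.341 with an estimated correlation). Egr2, an immediate-early transcription factor well above background on 5 of the 6 arrays, was at least 22.3-fold lower with the dim array at its floor, Hbegf, a growth factor, fell by 2.18 and Etv5, a transcription factor induced by ERK, by 1.43, and Areg, another growth factor, was at least 4.30-fold lower. Of 24 measured p53 targets 3 fell and 1 rose (3 and 1 adjusted over the list alone), with a median of -0.27 and camera adjusted p = 0.155 (0.043 without the background filter). Pmaip1, which promotes apoptosis, fell by 3.43, Tnfrsf10b by 1.45 and Phlda3 by 1.11, and Pltp, a lipid transfer protein, rose by 1.95. Cdkn1a, the p21 cell cycle inhibitor, differed by -3.14 ± 1.46 (adjusted p = 0.156, or 0.0156 with array weights); it differed by -4.71 without restricted mouse 1 (adjusted p = 0.0224) and by 0.02 with the slide as a block (adjusted p = 0.995).

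Genes of collagen-producing cells were lower, and endothelial genes were not. Of 23 measured collagen, stellate cell and fibroblast markers 14 fell and none rose (14 adjusted over the list alone), with a median of -1.29 and camera adjusted p = 1.14e-06 (adjusted p = 0.341 with an estimated correlation). Timp1, an inhibitor of matrix proteases, fell by 3.87 ± 0.29, Col3a1 by 2.55 ± 0.44 and Pdgfra by 1.20 ± 0.21. Of 20 measured liver endothelial markers 7 rose and 1 fell (8 and 1 adjusted over the list alone), with a median of 0.34. Oit3 rose by 2.08, Clec4g, a lectin of sinusoidal endothelium, by 1.86 and Flt4, well above background on 5 of the 6 arrays, was at least 2.30-fold higher with the dim array at its floor (not called with normexp background correction, adjusted p = 0.103), and Fcgr2b, a receptor that macrophages also carry, fell by 2.14. The endothelial list passed camera at adjusted p = 0.0403 (adjusted p = 0.544 with an estimated correlation), a call that ended with normexp background correction (0.123), quantile normalization (0.063), median scaling (0.0538), no background filter (0.106), probes well above background on all arrays (0.156), array weights (0.155) and the slide as a block (0.0678). It also ended when leaving out control mouse 1 (0.0593), control mouse 3 (0.129), restricted mouse 1 (0.0511) or restricted mouse 2 (0.0621).

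Oxidative phosphorylation and fatty acid oxidation genes were higher. Of 34 oxidative phosphorylation genes 33 rose (34 adjusted over the list alone), with a median of 1.09 and single differences between 0.65 and 1.85. Cyc1, of respiratory complex III, rose by 1.85 ± 0.21, Uqcrc1 by 1.77 ± 0.17, Sdhb, of complex II, by 1.60 ± 0.18 and Uqcrfs1 by 1.37 ± 0.16. The list passed camera at adjusted p = 1.17e-14 (adjusted p = 0.238 with an estimated correlation). Of 36 fatty acid oxidation and ketogenesis genes 28 rose and none fell (30 adjusted over the list alone), with a median of 1.33 and camera adjusted p = 1.25e-10 (adjusted p = 0.267 with an estimated correlation). Acaa1b, a peroxisomal thiolase, rose by 4.16 ± 0.37 and Eci1 by 2.17 ± 0.21, and Cyp4a31 and Cyp4a10, fatty acid hydroxylases saturated in all restricted mice, were at least 21.5-fold and 20.1-fold higher. Cpt1a, which admits fatty acids to mitochondria, rose by 0.95 ± 0.21 (adjusted p = 0.0164, or 0.0657 without restricted mouse 2). The fasting-induced genes Pdk4 (-2.33 ± 1.31, adjusted p = 0.232) and Fgf21 (-0.93 ± 0.70, adjusted p = 0.367) did not pass. With array weights Pdk4 was -3.98 (adjusted p = 0.0321). Its values were -0.10, 4.02 and -1.59 on the control diet and -0.79, -1.61 and -2.27 on the restricted diet. The weights were 2.38 for control mouse 2, which has the high value, and 0.37 for control mouse 3. Hepatocyte secreted protein genes, the markers of the main liver cell, had a median of 0.24, with 1 of 24 rising (1 adjusted over the list alone) and 14 saturated on all arrays (camera adjusted p = 0.116, or 0.0253 without control mouse 3 and 0.0428 without restricted mouse 2). Cebpa, a hepatocyte transcription factor, was the 1 that rose, by 1.60.

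Among de novo lipogenesis genes more rose than fell, as among those of fatty acid breakdown. Of 25 measured de novo lipogenesis genes 14 rose and 2 fell (14 and 4 adjusted over the list alone), with a median of 0.90 and camera adjusted p = 0.00245 (adjusted p = 0.292 with an estimated correlation). Scd1, a desaturase, rose by 2.92 ± 0.22 (adjusted p = 0.000389), Me1, malic enzyme, by 2.65, Acacb by 2.63 and Acss2 by 2.61. Fasn, fatty acid synthase, rose by 1.00 ± 0.23 (adjusted p = 0.0202), a call that ended without control mouse 1 (0.0709) or restricted mouse 2 (0.0678). Srebf1, a regulator of these genes, differed by 0.13 ± 0.51 (adjusted p = 0.877), with a sign that turned between settings. Cholesterol synthesis genes went both ways: of 25, 4 rose and 3 fell (4 and 3 adjusted over the list alone), with a median of -0.30 and camera adjusted p = 0.965. Among them Tm7sf2 rose by 1.59, Sc5d by 1.20, Acat2 by 0.97 and Ebp by 0.92.

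Glucose metabolism genes went both ways. Of 30 glycolysis and glucose uptake genes 9 rose and 5 fell (11 and 5 adjusted over the list alone), with a median of 0.36 and camera adjusted p = 0.331. Slc2a2, the glucose transporter of hepatocytes, rose by 1.76 and Pklr, the pyruvate kinase of liver, by 0.99 ± 0.20 (adjusted p = 0.0111). Pfkp fell by 3.88, Hk2 by 2.77 and Hk1 by 2.03, isoforms that many cells other than hepatocytes express; the other probe of Hk1 measured 0.48 and that of Pfkp measured -0.82. Of 30 gluconeogenesis and amino acid catabolism genes 14 rose and none fell (19 adjusted over the list alone), with a median of 0.74 (0.47 with quantile normalization) and camera adjusted p = 2.48e-06 (adjusted p = 0.267 with an estimated correlation). Hpd, which degrades tyrosine, rose by 1.64, Otc, of the urea cycle, by 1.58 and Gpt by 1.31. Pck1 and G6pc, of gluconeogenesis, did not pass: Pck1, saturated on 2 arrays, differed by 0.72 ± 0.22 (adjusted p = 0.0523, or 0.0373 with normexp background correction, 0.0266 with median scaling and 0.0313 with trend and robust moderation) and G6pc by -0.43 ± 0.80 (adjusted p = 0.725), with a positive sign without control mouse 2 or without restricted mouse 1. Of 30 insulin, IGF1 and fasting signalling genes 5 rose and 3 fell (5 and 3 adjusted over the list alone), with a median of 0.03 and camera adjusted p = 0.54. Igfbp3 rose by 2.07, Igfbp2 by 1.68 and Prkaa2, a catalytic subunit of AMPK, by 1.21, and Enho, the gene of adropin, fell by 3.06. Igf1 differed by -0.12 ± 0.17 (adjusted p = 0.624; its 4 other probes from -0.52 to 0.39) and Igfbp1, saturated on 3 arrays, by -0.91 ± 0.61 (adjusted p = 0.314, or 0.0365 without restricted mouse 1).

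Bile acid and detoxification genes were higher. Of 20 bile acid synthesis and transport genes 13 rose and none fell (15 adjusted over the list alone), with a median of 1.06 and camera adjusted p = 1.45e-05 (adjusted p = 0.238 with an estimated correlation). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, rose by 4.06 ± 0.94 (adjusted p = 0.0195), a call that ended without restricted mouse 1 (0.054) or restricted mouse 2 (0.0548). Cyp8b1 rose by 3.42, Akr1d1 by 1.95 and the sterol exporters Abcg8 and Abcg5 by 1.82 and 1.25. Of 35 measured NRF2 target and glutathione conjugation genes 19 rose and 1 fell (21 and 2 adjusted over the list alone), with a median of 0.82 (0.54 with quantile normalization) and camera adjusted p = 2.42e-06 (adjusted p = 0.238 with an estimated correlation). Those that rose include the glutathione transferases Gsta1 with 4.42 and Gstt3 with 2.82, and Ugdh, which makes UDP-glucuronic acid, with 2.02; Gsta1 and Gsta2 are near-identical and share signal. Of 28 measured phase I drug metabolism genes 18 rose and 1 fell (19 and 2 adjusted over the list alone), with a median of 0.96 and camera adjusted p = 5.49e-06 (adjusted p = 0.238 with an estimated correlation). Cyp2c55 rose by 2.56, Aldh1a1, saturated on 1 array, by 2.34, Ces2a by 2.16 and Cyp2c38 by 2.05 (its other probe measured 1.44).

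Male-biased liver genes were higher, and the female-biased list did not pass the test, though most of its called genes rose. Of 21 measured male-biased genes 15 rose and none fell (15 rose and 1 fell adjusted over the list alone), with a median of 2.12 and camera adjusted p = 8.03e-06 (adjusted p = 0.341 with an estimated correlation). Besides Cyp4a12a and Mup21, Nudt7, a peroxisomal hydrolase, rose by 2.67 and Ugt2b38 by 1.55. Of 21 measured female-biased genes 6 rose and 1 fell (7 and 1 adjusted over the list alone), with a median of 0.41 and camera adjusted p = 0.347. Cyp2a4 and Cyp4a14, saturated in all restricted mice, were at least 9.19-fold and 7.05-fold higher. Cyp2b9 rose by 2.23 and Cyp3a16 by 1.41. The related Cyp2a22 rose by 3.80, and signal shared within the Cyp2a and Cyp4a families cannot be separated. Of the 21 female-biased genes 9 are also in other lists.

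Genes of the amino acid response and ER stress were lower, and the autophagy and adipose lists were higher by less and depended on the setting. Of 26 measured genes of the amino acid response, serine synthesis and ER stress 14 fell and 1 rose (15 and 1 adjusted over the list alone), with a median of -1.03 and camera adjusted p = 4.65e-05 (adjusted p = 0.337 with an estimated correlation). Nupr1, a stress-induced regulator, fell by 2.70, and the ER chaperone partners Sdf2l1 and Manf fell by 1.94 and 1.40. Of 25 autophagy and lysosome genes 5 rose and none fell (5 adjusted over the list alone), with a median of 0.36 and camera adjusted p = 0.0403 (adjusted p = 0.566 with an estimated correlation), a call that ended without control mouse 3 (0.194) or restricted mouse 1 (0.183). It also ended with normexp background correction (median 0.20, adjusted p = 0.0932), quantile normalization (0.245), median scaling (0.0623), no background filter (0.113), probes well above background on all arrays (0.0708) and array weights (0.109). Bnip3 rose by 1.38, and Gabarapl1, saturated in all restricted mice, was at least 2.22-fold higher. Of 13 measured adipose tissue markers 4 rose and 1 fell (5 and 1 adjusted over the list alone), with a median of 0.58 and camera adjusted p = 0.0344 (adjusted p = 0.267 with an estimated correlation), a call that ended without control mouse 3 (0.101) or restricted mouse 1 (0.0511), and with normexp background correction (median 0.29, adjusted p = 0.0526), no background filter (0.128) and array weights (0.0881). Besides Car3, Sncg, well above background on 5 of the 6 arrays, was at least 3.52-fold higher with the dim array at its floor, and Lipe rose by 1.13 and Pnpla2 by 0.98, the last pair being lipases.

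Of 19 measured circadian clock genes 6 rose and none fell (6 adjusted over the list alone), led by Usp2 with 3.09, while Nr1d2 with 0.89 (adjusted p = 0.0147) lost its call without control mouse 1 (0.0551) or restricted mouse 2 (0.0543), and camera gave adjusted p = 0.187 around a median of 0.27. Of 38 cytosolic ribosomal protein genes none passed the test (none adjusted over the list alone), with Rpl3 at -0.57 and Rpl13 at -0.33. Their median was -0.16 with camera adjusted p = 0.386, but quantile normalization called the list lower (median -0.46, adjusted p = 2.81e-05). Of 14 heat shock genes 2 rose (2 adjusted over the list alone; median 0.16, camera adjusted p = 0.371), namely Hspd1 with 0.87 (adjusted p = 0.0142, or 0.0554 without control mouse 2 and 0.0609 without restricted mouse 2) and Dnaja1 with 0.90 (adjusted p = 0.0186, or 0.0512, 0.0548 and 0.0679 without control mouse 1, restricted mouse 1 and restricted mouse 2). With quantile normalization Hspd1 was 0.53 (adjusted p = 0.0827) and Dnaja1 was 0.58 (adjusted p = 0.0696). Of 13 measured erythroid markers 5 rose and 2 fell (5 and 2 adjusted over the list alone), including Klf1 with 1.46 and Fech with 0.97, around a median of 0.06 (camera adjusted p = 0.43). Of 16 measured cholangiocyte markers 1 rose, Krt23, and 3 fell (1 and 5 adjusted over the list alone), among them Spp1 by 2.33, around a median of -0.51 (camera adjusted p = 0.333, or 0.0431 on slide 1 alone). That median was -0.24 with normexp background correction, -0.18 for probes well above background on all arrays and -0.20 without restricted mouse 1. Epcam was at least 1.81-fold lower, without a call under normexp background correction (adjusted p = 0.591). Of 7 measured exocrine pancreas markers 3 rose (3 adjusted over the list alone), with Ctrb1 at 1.09 and Sycn at 0.82 (adjusted p = 0.0145, or 0.0566 without control mouse 2 and 0.0943 with normexp background correction), a median of 0.35 and camera adjusted p = 0.0751 (median 0.50, adjusted p = 0.0204 with quantile normalization).

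**Figure D2:**
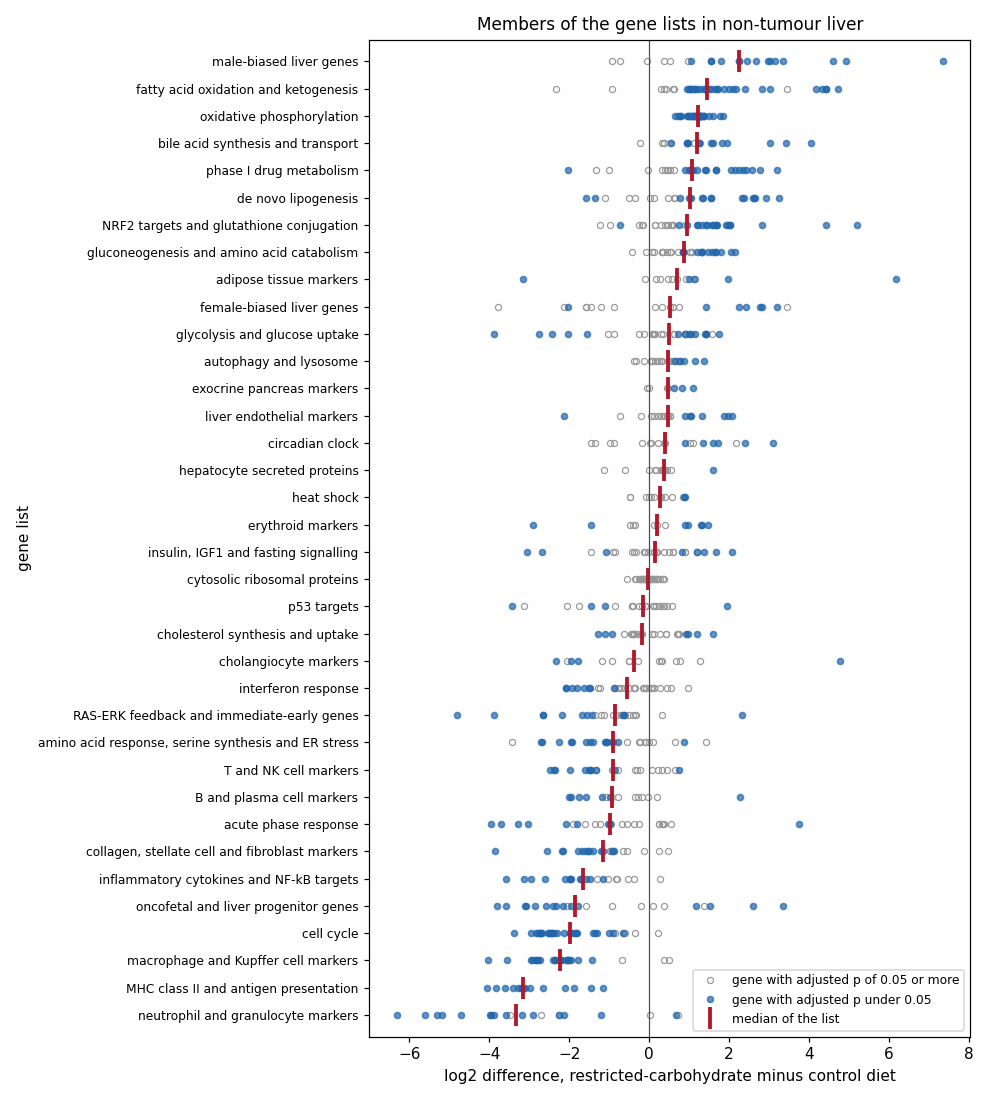
Log2 difference between the diets (horizontal axis, restricted minus control, as fitted) for each measured member of the 36 gene lists (vertical axis, ordered by median). Filled points are genes with adjusted p under 0.05, open points the others, and vertical bars list medians. All 15 antigen presentation genes lie to the left of 0 and all 34 oxidative phosphorylation genes to the right.

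In all, camera called 24 of 36 lists, 11 higher and 13 lower. When the arrays were split with the diets mixed, camera still called 5 to 27 lists. The groups of those splits held unequal numbers of each diet, so they are not free of a diet difference. With an estimated correlation it called none, and 7 had an unadjusted p under 0.05. The limma test of each gene does not use that correlation. Counts of correlated members called in the same mice can still be raised by it. In a single direction fry called 23 lists, 19 of them shared with camera; it did not call the T and NK (adjusted p = 0.0707), B (0.0739), interferon (0.225), acute phase (0.122) and autophagy (0.0607) lists, and it called the pancreas (0.0159), p53 (0.0224), circadian (0.0224) and heat shock (0.0479) lists. The control mice and restricted mouse 1 shared a slide: with the slide as a block 3013 features changed (1121 higher, 1892 lower), on that slide alone 2444 did, and the medians of the macrophage, cell cycle, oxidative phosphorylation and male-biased lists with the block were -2.60, -2.28, 1.17 and 2.21, and -2.62, -2.31, 1.15 and 2.14 on the slide alone. Both fits compare restricted mouse 1 with the control mice, so they are not separate checks. Among the genes named above as changed, the block ended the calls of Clec2h, Pklr, Fasn, Cpt1a, Cyp7a1, Afp, Sc5d, Akr1d1, Abcg5, Manf, Cyp3a16, Cyp2b9, Gabarapl1, Bnip3, Klf1, Hspd1, Dnaja1, Nr1d2, Sycn, Lipe and Ctrb1. The fit on slide 1 alone also ended those of Acat2, Ebp, Cyp8b1, Pltp, Phlda3, Hbegf, Cebpa, Cyp4a14, Prkaa2, Oit3, Clec4g, Flt4, Cd6, Fech, Sncg and Pnpla2. All kept their sign, with values under the block of 4.37 for Cyp7a1, 0.97 for Cpt1a, 0.71 for Fasn and -0.94 for Manf. Without control mouse 2 the number of changed features was 3357, and without restricted mouse 2 it was 3430.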

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

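No called gene among those named, and no called gene list, reversed its direction under the alternatives that give a value for it. The fit on every probe, the pooled test and the other thresholds were compared by counts alone, and the other probes of Hk1 (0.48) and Cd6 (0.81) have the opposite sign. Medians of some lists that were not called changed sign: after subtracting the median of all features, the hepatocyte and heat shock lists were each -0.07 with quantile normalization, the insulin list was -0.03 with normexp background correction, -0.11 without the background filter, -0.03 for probes well above background on all arrays and -0.14 with array weights, the erythroid list was -0.07 with normexp background correction or no background filter, -0.05 with array weights, -0.08 with the slide as a block and -0.10 with slide 1 only (both lists also when some mice were left out), and the cholesterol list was 0.05 without control mouse 1 (fry gave it the direction opposite to camera). Of 5386 genes past the threshold (2868 higher, 2518 lower), array weights gave 8368 (4863 higher), the slide as a block 3013 (1121 higher) and slide 1 only 2444 (842 higher, 1602 lower), the last from fewer arrays. An ordinary pooled test gave 1632 lower and a 2-fold limit left 1572 higher. Leaving out 1 mouse gave 3357 to 5889 genes (1580 to 3308 higher, 1766 to 2581 lower). The share of calls that were higher was 53.2%, against 61.2% with median scaling and 37.2% with the slide as a block. The gene lists called went from 24 to 0 with an estimated correlation, and were 21 to 24 when 1 mouse was left out. Some genes that did not pass the threshold changed sign. Trp53 was 0.11 with normexp background correction and -0.41 to 0.13 with 1 mouse left out. Srebf1 was -0.60 with the slide as a block or slide 1 only, and -0.33 to 0.49 with 1 mouse left out, and G6pc was -1.18 to 0.24. With the slide as a block or slide 1 only, Fgf21 was 0.10, Igfbp1 was 0.46 and Cdkn1a was 0.0185. The cause was not tested. Deviations from the group means correlated at 0.384, -0.00244 and 0.482 between mice of the same number. Between mice 1 and 3 of opposite diets the correlation was -0.384 and -0.499. Mouse 2 does not correlate best with its own number. The labels do not say that the numbers mark a litter, cage or day, so they were not taken as pairs in the main fit. Whether they mark pairs cannot be told. The second principal component (15.2% of the variance) did run in the order of the numbers. It was 30.3, 14.8 and -50.3 on the control diet and 43.0, -1.11 and -36.7 on the restricted diet. With the number as a block 6623 genes passed, and Cdkn1a did (adjusted p = 0.0313). Low signal limits the bounds given for dim probes, and 109 saturated features cannot show a difference. The offset of the normexp setting shrinks the differences of dim probes, so its smaller values and lost calls for them partly follow from the setting.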

Other observations

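Gene families outside the fixed lists, chosen after values were seen, held more called genes in a single direction than other features did. Of 48 measured Mrpl genes, which encode proteins of the mitochondrial ribosome, 24 rose and none fell (adjusted p = 8.63e-07 by Fisher's exact test), as did 18 of 29 Mrps genes (adjusted p = 8.63e-07 by the same exact test). Of 15 Pex genes, which build peroxisomes, 10 rose (adjusted p = 0.000502, exact test), and of 10 Ugt genes, which attach sugar groups, 8 rose (adjusted p = 0.000502, exact test). Of 10 Klra genes, receptors of NK cells, 7 fell (adjusted p = 0.00387, exact test), of 12 Tlr genes 7 fell and 2 rose (adjusted p = 0.0123, exact test) and of 21 Clec genes 11 fell and 4 rose (adjusted p = 0.0021, exact test). In all 239 families were tested, 13 passed as higher and 10 as lower. Genes of a family are not independent and near-identical members share signal.

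The tests below were written after values were seen, except those on the slide, on brightness and GC content, and on splits. List medians here are as fitted, without subtracting the median of all features. The bootstrap intervals resample the genes of a list and not the mice, so they do not measure the spread between mice. A smaller share of all non-hepatocyte cells in the restricted samples would lower endothelial genes too. The endothelial median lay 2.70 above the macrophage median (95% bootstrap interval 2.43 to 3.25) and was 0.46 itself. That argues against a smaller share of all these cells alike. A smaller share of leukocytes and collagen-producing cells alone was not tested. With the slide as a block the macrophage median was -2.48 (camera adjusted p = 2.13e-15, no exact test), a comparison that rests on restricted mouse 1, which argues against the slide as the cause for that list. Without the block that list had adjusted p = 0.238 with an estimated correlation (no exact test). Transduced or tumour cells in the control samples stay open: the Hras probe differed by 0.389 and may not read the human transgene.

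The oxidative phosphorylation median, as fitted, lay 1.05 above that of the 4 of 24 hepatocyte genes saturated on no array, with an interval of -0.399 to 2.34, so a larger hepatocyte share could explain it or not. After removal of trends with brightness and GC content the median was 0.914 (0.863 to 0.995), which argues against those as the cause. Without Mup and Cyp4a members the male-biased median was 1.55 (0.448 to 2.64), which argues against signal shared within those families as the whole cause. Signal shared within other families was not tested. The members left include Ugt2b38, and its relative Ugt2b5 rose by 1.63. The female-biased median, as fitted, was 0.53 (-1.20 to 1.41), so a growth hormone pattern more typical of males stays open.

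Of the 10 ways to split the 6 arrays into 3 and 3, only 1, the real one, gave as many genes (5386, against 0 as the highest other), and 2 gave as many lists (24 for the real split, 27 as the highest other). The splits are too few for a share under 0.05. The other splits, which mix the diets, gave 5 to 27 lists while calling no gene. The number of lists called by camera at its preset correlation therefore does not set the real split apart. Its small adjusted p values for lists are not by themselves evidence of a diet difference. The groups of the other splits still hold unequal numbers of each diet, so those splits are not free of a diet difference either.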
